A study of Arabidopsis thaliana with 18 samples.

How the data were processed

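Leaves of Arabidopsis thaliana Col-0 and of a 35S:RPS4 line, grown at 28 °C, were taken before and 4 h and 8 h after a shift to 19 °C, with 3 libraries in each of 6 groups. Per the labels total RNA was extracted with DNase treatment, depleted of ribosomal RNA and made into poly-A libraries sequenced on a HiSeq2000. The processing notes name TopHat2 2.0.0, BWA 0.5.9 and the TAIR10 build, without their order or roles. The deposited tables give, in each library, expected counts of reads (whole numbers for junctions, steps of 0.5 in some retained introns) for each splice junction and each retained intron, with chromosome, first and last intron base, gene and a type code. The codes are NJ, A3P, A5P, ES, CI and IR; their meaning and the strand are not given in the sources used here. Row structure was checked: 32947 of 34785 A3P junctions share only their lower coordinate with an NJ junction, 34975 of 36857 A5P junctions only their upper, and 78294 of 87935 retained introns are also NJ introns. Main junctions are of type NJ. No genome or annotation of the build was used here; a reference table of TAIR10.1 gave gene symbols and matched 19875 of 19926 gene identifiers.

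Repeated rows (706 to 1231 per library) were merged and counts rounded to whole numbers. Of 280391 features, 5685 name several genes; they held 0.144% to 0.217% of reads and were left out of the gene sums. A gene's count was the sum of reads over its junctions of all types but IR, so a read that crosses 2 junctions may count in both, and genes without introns have no value. A feature without a row in a library was taken as 0. Such zeros were searched for where at least 20 reads were expected: 1237 were found among 1200244 values.

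Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, filterByExpr, TMM scaling, 1 model of 6 groups and 18 libraries) in R 4.3.3. Comparisons were 35S:RPS4 against Col-0 at each time, 4 h and 8 h against 0 h in each line, and the difference of these responses between the lines. P-values were adjusted over genes by the Benjamini and Hochberg method, and genes at or under 0.05 were called without a threshold on fold change. Libraries of 14692560 to 24242900 junction reads and a common biological coefficient of variation of 22.3% set the precision. DESeq2 1.42.0 was run as the other tool. Tables were made with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with matplotlib 3.10.9.

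Splicing was tested with diffSpliceDGE of edgeR, which asks whether a feature's change differs from that of the rest of its gene. Features needed at least 10 reads in at least 3 libraries, feature p-values were joined per gene by the Simes method, and gene p-values were adjusted over genes. Percent retained is retained reads over retained plus spliced reads of the same intron. Genes of a list were compared with other genes for splicing calls by Fisher's exact test, adjusted over the lists. Genes were not matched for read depth in this test.

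Gene lists, 20 with 346 entries, were written from general knowledge before the data were examined, as were the comparisons, tests and the alternatives named first below. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry; p-values were adjusted over the lists of a comparison. Members were called over all genes and adjusted over the list alone. The last 3 lists hold markers of cell types and are reported as lists.

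Genes are named by a rule: in each comparison, among genes with an adjusted p under 0.05, a mean of at least 10 CPM over all libraries and no overlap between the libraries of the 2 groups (for a difference of responses, of the lines at that time), the 10 with the highest and the 10 with the lowest log2 fold change, with RPS4 and list members besides. For splicing the rule takes the 10 genes with the lowest adjusted p with their lowest-p feature, RPS4, and the NLR and splicing factor genes called. Folds are ratios of a group's summed reads over its summed scaled library sizes, which can differ from the ratio of mean CPM, and for RPS4 the fitted ratio. Where a group had 0 reads the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts it is given with an exact 95% counting interval where a value is quoted for its size.

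Relations between retention and transcript change were examined in 4 comparisons of time. Transcript change came from replicate 1 and retention change from replicates 2 and 3, so that no library entered both. Introns were kept by minimum reads, among them retained reads summed over both times, in the libraries that gave retention change. Introns of genes that rose can pass mainly through the later time, and those of genes that fell through 0 h. This selection can push retention change toward the direction of gene change. The tests were tested on simulated data. In the 4 h comparison of the lines 100 genes each were given 2-fold and 4-fold changes, as many up as down. Of these 57% and 87% were recovered, and 5.88% of calls were false. The rest of 15227 genes were left unchanged, whereas in the data 6882 of 15498 were called at 4 h. The shares so hold for few changed genes and need not hold for the data. For splicing, simulated in the same way, 2% and 67% were recovered, and 4.17% of calls were false. Median log2 changes in use over all altered features, recovered or not, were 0.75 and 1.62. Altered features were picked by a minimum of reads and a limited share of their gene, and recovery was counted whatever the direction. Reads spread unevenly along genes and missing rows were not simulated. The shares for splicing therefore need not hold for the data either.

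Alternatives chosen before the data were examined were RLE scaling, no low-count filter, DESeq2, only the libraries of the groups compared, replicate number as a block, each library left out in turn, a stricter minimum of 30 reads for features, features compared only with those sharing an end, and the other list tests. Those chosen after the data were seen were total counts without a scaling factor, retained reads added to gene sums, NJ junctions only, junctions with missing rows left out, splice junctions only, and 3 Col-0 libraries removed (0 h replicate 2, 8 h replicates 2 and 3), of which 8 h replicate 3 was added after coverage along genes had been measured. That removal left only replicate 1 of Col-0 at 8 h. A test of annotated features only was not run, since no annotation of the build was used here, and pseudocount alternatives did not apply to counts. Other splits of the libraries were refitted for every comparison.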

Results

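The data were RNA sequencing libraries from leaves of 3.5-week-old Arabidopsis thaliana plants of the accession Col-0 and of a line that overexpresses RPS4 from the 35S promoter (35S:RPS4). RPS4 is an intracellular immune receptor of the TIR-NLR class, and per the labels immunity in this line can be switched on by a shift from 28 °C to 19 °C. Leaves were taken before the shift (0 h) and 4 h and 8 h after it, with 3 libraries in each of the 6 groups of line and time, 18 in all. The tables gave reads over splice junctions and reads retained in introns, with coordinates on the TAIR10 genome build. Libraries held 14692560 to 24242900 reads over splice junctions. Junction reads were summed per gene, and 15498 genes were tested. Genes without introns, among them PR1, had no value, and 28 of the 346 entries of the gene lists had no junction reads.

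Libraries of a group resembled each other (Pearson r across genes 0.959 to 0.989), and genes are not independent replicates in such a correlation. The first principal component held 63.2% of the variance. It set the 35S:RPS4 libraries at 4 h (scores 76.8 to 103.4) and at 8 h (202.4 to 217) apart from the other 12, which lay between -88.9 and -60.3. The second held 13.1% and set Col-0 at 8 h (83 to 106.8) apart. Levels are given as CPM (junction reads scaled to library size with TMM factors), as mean ± SD with n = 3 libraries per group. Adjusted p-values measure the spread between libraries, which may be technical, since the labels do not say whether replicates were separate plants.

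The RPS4 transcript (AT5G45250, chromosome 5) was the basis of the system. Its level in the 35S:RPS4 line was 187.9 ± 37.6 CPM at 0 h, 437.4 ± 67.8 CPM at 4 h and 157.6 ± 12.2 CPM at 8 h (SD, n = 3). In Col-0 it was 2.57 ± 0.291, 3.06 ± 0.609 and 3.08 ± 0.766 CPM. All 3 libraries of the line lay above all 3 of Col-0 at each time, and the fitted ratios were 73-fold at 0 h (adjusted p = 6.02e-11), 143-fold at 4 h (adjusted p = 8.89e-13) and 51-fold at 8 h (adjusted p = 2.76e-12). Between 0 h and 4 h the transcript rose 2.33-fold in the line (log2 change 1.22, SE 0.177, adjusted p = 2.1e-05), and at 8 h it did not differ from 0 h by the test (log2 change -0.25, adjusted p = 0.198). In Col-0 the log2 changes were 0.25 at 4 h (adjusted p = 0.451) and 0.27 at 8 h (adjusted p = 0.352). The rise at 4 h exceeded that in Col-0 by 0.965 on the log2 scale (SE 0.284, adjusted p = 0.0146); with scaling by total counts alone this difference was 0.755 and did not pass.

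**Figure D1:**
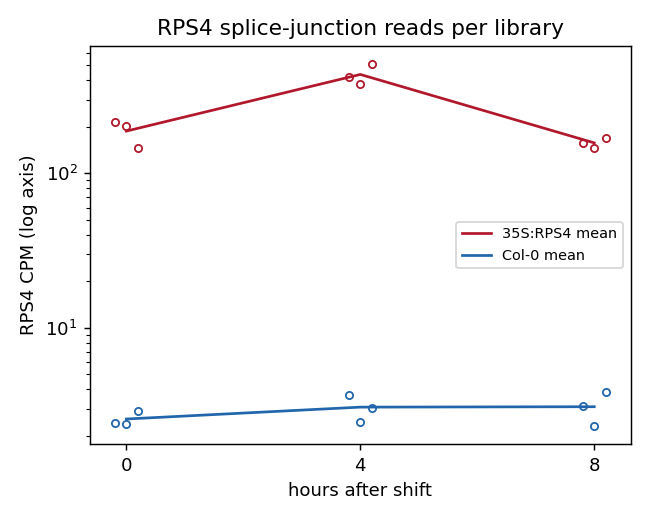
RPS4 level in CPM of junction reads (vertical, log axis) against hours after the shift (horizontal) in 35S:RPS4 and Col-0; points are libraries and lines join group means. The line's libraries lie between 145.1 and 510.8 CPM with the highest mean, 437.4 CPM, at 4 h, and those of Col-0 lie between 2.31 and 3.84 CPM.

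Before the shift the comparison asks how the lines differed while immunity was not switched on. Only 1 35S:RPS4 line was sampled, so effects of the transgene and other differences between the lines cannot be separated. Besides RPS4, AT5G24240 was higher in the line, with 279 reads in the line and 0 in Col-0, at least 94.1-fold (adjusted p = 0.00585), and its level in the line was 5.38 ± 0.909 CPM. AT4G04223 was 3.63-fold higher (11.7 ± 1.01 against 3.22 ± 1.14 CPM, adjusted p = 0.0313); it lies outside the rule for named genes and was chosen after its values were seen. It did not pass with replicate number as a block, with total counts only, with only the groups compared, or when any 1 of the 35S:RPS4 0 h libraries or Col-0 0 h replicate 3 was left out. No gene was lower in edgeR. EDS1 and ICS1 did not pass in edgeR at this time: EDS1 had 4.60 ± 0.900 CPM in the line and 5.35 ± 0.369 in Col-0, and ICS1 15.5 ± 1.05 and 10.1 ± 1.04.

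Of 15498 genes, 3 passed at 0 h, while 1221 had an unadjusted p under 0.05 and DESeq2 called 115 (12 higher, 103 lower). In edgeR no member of any list passed over all genes, while DESeq2 called 7 genes of the jasmonate list. Adjusted over the list alone, 15 of 19 measured members of the jasmonate and ethylene list and 10 of 10 of the cold response list were lower in the line. Both lists were called lower by camera (adjusted p = 1.33e-12 and 3.44e-14), and neither with an estimated correlation (adjusted p = 0.242 for both). The surface receptor (adjusted p = 0.00015), WRKY (0.0072) and ER folding (0.0282) lists were also called lower and the ribosome biogenesis (0.000298) and photosynthesis (0.0238) lists higher, none of them with an estimated correlation (adjusted p = 0.242, 0.242, 0.644, 0.242 and 0.768). The Col-0 libraries at 0 h were uneven in the jasmonate list: their mean log2 levels relative to all libraries were -0.49, 2.24 and 2.13, against 0.1, -1.12 and 0.01 in the line. Without Col-0 0 h replicate 1 edgeR called 194 genes (9 higher, 185 lower), 13 of them on the jasmonate list.

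At 4 h after the shift the 35S:RPS4 line had immune genes of many kinds at higher levels than Col-0. EDS1 (AT3G48090), the lipase-like regulator needed for signalling by TIR-NLR receptors, stood at 524 ± 69.3 CPM against 6.96 ± 1.63 in Col-0 (n = 3 each), 74.6-fold higher. ICS1 (AT1G74710), the isochorismate synthase of salicylic acid (SA) synthesis, was 193-fold higher, at 3248 ± 752 against 16.6 ± 2.59 CPM, and every library of the line lay above every library of Col-0. Among the lower genes were ACL5 (AT5G19530), thermospermine synthase, 83.5-fold (0.406 ± 0.559 against 30.3 ± 6.79 CPM), and BR6OX2 (AT3G30180), which makes brassinolide, 26.1-fold (0.513 ± 0.297 against 13.4 ± 1.24 CPM).

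The genes highest above Col-0 at 4 h under the naming rule included BON3 (AT1G08860), a copine, at 53.3 ± 15.6 CPM and with 0 reads in Col-0 (at least 1050-fold higher), and AT5G36260 (at least 978-fold). AT3G54150 was 4370-fold higher (95% counting interval 1500 to 21200), AT2G20142 1620-fold and AT5G52760 1360-fold. The lowest also included COL2 (AT3G02380), 26.3-fold, FMO GS-OX3 (AT1G62560), an enzyme of aliphatic glucosinolates, 22.9-fold, and HBI1 (AT2G18300), a growth-promoting bHLH factor, 19.4-fold. No library of the line overlapped a library of Col-0 in any of these genes. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

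The SA and EDS1 list had 22 of 25 measured members higher and 0 lower at 4 h. CBP60g and SARD1, transcription factors that activate ICS1, were 1220-fold and 539-fold higher (959 ± 99.1 and 1598 ± 273 CPM against 0.784 ± 0.430 and 2.94 ± 0.715), and PAD4, the partner of EDS1, was 155-fold higher. The list was called higher with a preset correlation (camera adjusted p = 6.8e-17) and with an estimated correlation (adjusted p = 0.00254). Among WRKY transcription factors 23 of 24 were higher (adjusted p = 4.89e-12, and 0.00664 with an estimated correlation): WRKY46 stood at 1060.0 ± 87.3 against 1.91 ± 0.338 CPM and WRKY33 at 599.6 ± 128 against 2.76 ± 0.956. All 15 measured members of the surface receptor and signalling list were higher (adjusted p = 4.89e-12, and 0.0275 with an estimated correlation). They included the MAP kinase gene MPK3 at 902 ± 220.0 against 17.3 ± 1.89 CPM, the co-receptor gene BAK1 at 270.5 ± 54.4 against 19.6 ± 1.92, and RBOHD, the NADPH oxidase of the immune oxidative burst, at 377 ± 63.8 against 13.1 ± 1.58.

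Intracellular NLR receptor genes were higher at 4 h in 16 of 16 measured members (adjusted p = 4.64e-09, and adjusted p = 0.0572 with an estimated correlation). SNC1 stood at 56.6 ± 11.5 against 12.2 ± 0.685 CPM and RRS1, the receptor paired with RPS4, at 14.4 ± 2.27 against 6.52 ± 1.18. Of the camalexin and indole glucosinolate list, 12 of 12 were higher (adjusted p = 1.7e-08, and 0.0275 with an estimated correlation). CYP81F2, an indole glucosinolate hydroxylase, stood at 99.6 ± 24.5 against 0.237 ± 0.293 CPM and PAD3, the last enzyme of camalexin synthesis, at 13.3 ± 5.72 against 0.0485 ± 0.0839. The jasmonate and ethylene list had 14 of 19 members higher (16 adjusted over the list alone; adjusted p = 4.37e-05, and adjusted p = 0.382 with an estimated correlation). TAT3, a jasmonate-induced aminotransferase, stood at 1868 ± 191 against 10.6 ± 5.80 CPM and LOX4, a lipoxygenase of jasmonate synthesis, at 305 ± 34.9 against 3.21 ± 1.4. Of senescence and cell death genes 7 were higher and 1 lower of 11 (adjusted p = 0.00154, and adjusted p = 0.194 with an estimated correlation), with SAG21 at 1208 ± 226 against 1.94 ± 0.256 CPM and the copine gene BON1 at 4176 ± 169 against 21 ± 2.22. The gene SAG29 was the lower member. Pathogenesis-related genes had 3 of 4 higher (adjusted p = 0.16), with PR5 at 39.3 ± 9.38 against 20.2 ± 5.43 CPM.

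Heat shock genes were higher in the line in 10 of 12 members at 4 h (adjusted p = 9.97e-05, and adjusted p = 0.0807 with an estimated correlation). The chaperone genes HSP90.1 and HSP101 are examples, HSP90.1 at 188 ± 83.1 against 10.9 ± 3.99 CPM and HSP101 at 14.5 ± 8.82 against 2.33 ± 1.02. At 0 h their means were 199.5 and 51.4 CPM in the line and 185.6 and 56.1 in Col-0. Neither mean had thus risen in the line by 4 h, and both had fallen further in Col-0. Aliphatic glucosinolate genes were lower in 7 of 11 and higher in 1 (adjusted p = 0.00238, and adjusted p = 0.395 with an estimated correlation). MYB28 and MYB29, which activate this pathway, stood at 0.530 ± 0.329 and 0.104 ± 0.0624 CPM against 10.3 ± 2.82 and 11.7 ± 4.1, and FMOGS-OX1 was the higher member. Photosynthesis genes were lower in 6 of 25 (3 adjusted over the list alone; adjusted p = 0.0424, and adjusted p = 0.63 with an estimated correlation). The remaining lists were not called at 4 h. Their members higher and lower were 0 and 3 of 10 for cold response (2 lower adjusted over the list alone; adjusted p = 0.259) and 1 and 3 of 5 for growth at warm temperature (0.33). The circadian clock list had 2 and 7 of 18 (2 and 11 adjusted over the list alone; 0.0562). The other counts were 9 and 1 of 31 for splicing factors (5 and 1 adjusted over the list alone; 0.0854), 4 and 0 of 14 for ER folding (0.299) and 0 and 0 of 7 for ribosome biogenesis (0.793). For cell type markers they were 0 and 5 of 13 for guard cell and epidermis (0.0536), 0 and 1 of 10 for vascular tissue (0 adjusted over the list alone; 0.981) and 0 and 2 of 4 for meristem, flower and root (0.139).

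By edgeR's quasi-likelihood test 3474 genes were higher and 3408 lower at 4 h, of which 2389 and 1909 changed at least 2-fold. Scaling by total counts alone moved the median log2 change of all genes by -0.283 and the share of called genes that were higher from 50.5% to 31.6%, so small changes are relative to the scaling. Adjusted over the list alone, the counts above were the same except where another is given.

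**Figure D2:**
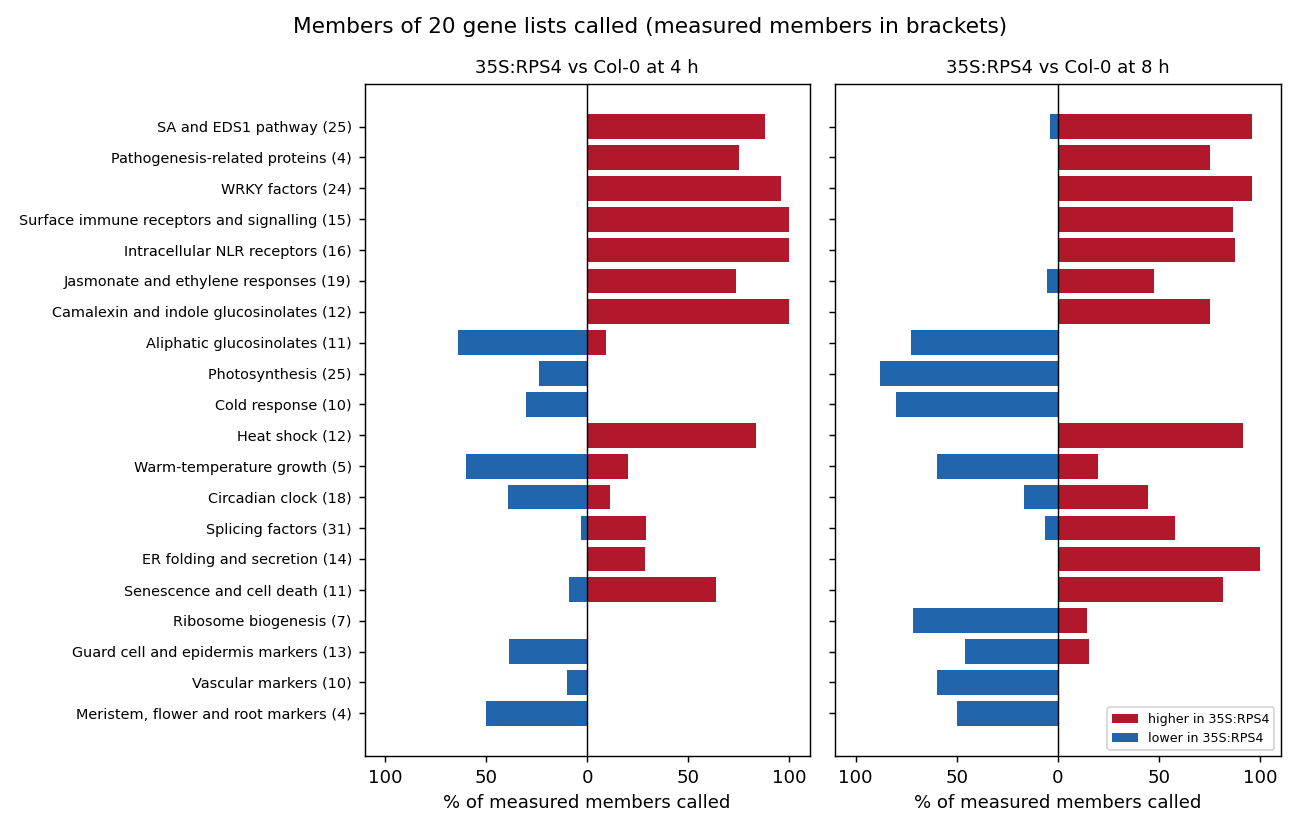
Share of each list's measured members called higher (red) or lower (blue) in 35S:RPS4 than in Col-0 at 4 h and 8 h (horizontal, percent; 20 lists on the vertical axis). At 8 h 14 of 14 ER folding genes were higher and 22 of 25 photosynthesis genes lower, against 4 and 6 at 4 h.

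By 8 h the line held high SA-pathway transcripts, and secretory chaperone genes were higher and photosynthesis genes lower than in Col-0. ALD1 (AT2G13810) and FMO1 (AT1G19250), enzymes of N-hydroxypipecolic acid synthesis, stood at 1523 ± 168 and 504 ± 173 CPM against 0.395 ± 0.467 and 0.122 ± 0.0339 in Col-0 (n = 3 each), 3960-fold and 3970-fold higher. BIP1 (AT5G28540), the main chaperone of the endoplasmic reticulum (ER), was 9.27-fold higher (1251 ± 155 against 135 ± 15.5 CPM). LHCB2.2 (AT2G05070), a light-harvesting protein, was 18.5-fold lower (22.4 ± 2.09 against 413 ± 80.9 CPM) and PRK (AT1G32060), phosphoribulokinase of the Calvin cycle, 7.34-fold lower (194 ± 13.6 against 1409 ± 59.3 CPM).

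Among the 10 highest genes under the naming rule at 8 h were MSRB7 (AT4G21830), a methionine sulfoxide reductase, at least 1810-fold higher, AT4G39020, at least 1820-fold, CYP71A12 (AT2G30750), an enzyme of camalexin synthesis, at least 1540-fold, and CRK37 (AT4G04500), a receptor-like kinase, 8600-fold (95% counting interval 1540 to 340000). Among the 10 lowest were AT3G15720, at least 966-fold, EXPA11 (AT1G20190), an expansin, at least 435-fold, PDCB3 (AT1G18650), a callose-binding protein of plasmodesmata, at least 340-fold, and PDLP3 (AT2G33330), a plasmodesmal protein, 2020-fold (95% counting interval 363 to 79900).

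Of the SA and EDS1 list 24 of 25 members were higher at 8 h and EPS1, an acyltransferase linked to SA synthesis, was lower (0.0984 ± 0.105 against 0.680 ± 0.271 CPM). The list was called with a preset (adjusted p = 4.8e-10) and an estimated correlation (adjusted p = 0.0224). WRKY genes were higher in 23 of 24 (adjusted p = 3.4e-06, and adjusted p = 0.0817 with an estimated correlation), with WRKY70 at 1025 ± 5.47 against 30.1 ± 4.17 CPM. Surface receptor genes were higher in 13 of 15 (adjusted p = 0.000223, and adjusted p = 0.254 with an estimated correlation), and FRK1, a kinase gene induced by bacterial flagellin, stood at 266 ± 52.9 against 0.962 ± 1.48 CPM. NLR genes were higher in 14 of 16 (adjusted p = 0.000649, and adjusted p = 0.275 with an estimated correlation). Camalexin and indole glucosinolate genes were higher in 9 of 12 (adjusted p = 0.0117, and adjusted p = 0.275 with an estimated correlation), with PAD3 at 91.9 ± 12.3 CPM against 0.0355 ± 0.0615. MPK3, at 104 ± 14.4 CPM, was 5.04-fold above Col-0. Heat shock genes were higher in 11 of 12 (adjusted p = 0.000377, and adjusted p = 0.221 with an estimated correlation), HSP90.1 at 572 ± 90.3 against 1.17 ± 0.119 CPM. Senescence and cell death genes were higher in 9 of 11 (adjusted p = 0.00232, and adjusted p = 0.254 with an estimated correlation), SAG13 at 58.9 ± 2.76 against 0.119 ± 0.0564 CPM. Pathogenesis-related genes had 3 of 4 higher (adjusted p = 0.164), among them PR2, a glucanase, at 11.5 ± 3.41 against 0.121 ± 0.135 CPM. The jasmonate and ethylene list had 9 members higher and 1 lower of 19 (8 and 1 adjusted over the list alone; adjusted p = 0.111); TAT3 stood at 11830.0 ± 1500.0 against 8.19 ± 6.26 CPM and the defensin gene PDF1.2 was lower.

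All 14 measured members of the ER folding and secretion list were higher at 8 h (adjusted p = 3.4e-06, and adjusted p = 0.254 with an estimated correlation). CNX1, calnexin, stood at 1086 ± 133 against 169.8 ± 37.0 CPM, CRT3, a calreticulin, at 1746 ± 37.1 against 182 ± 79.5, and BZIP60, a factor of the unfolded protein response, at 83.3 ± 4.51 against 6.61 ± 2.05. Splicing factor genes were higher in 18 and lower in 2 of 31 (18 and 1 adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.275 with an estimated correlation). RS31, an SR protein gene, stood at 157 ± 9.65 against 39.1 ± 6.01 CPM and SR45A at 33.5 ± 6.99 against 9.09 ± 1.74. Photosynthesis genes were lower in 22 of 25 (adjusted p = 3.03e-07, and adjusted p = 0.275 with an estimated correlation), and RCA, Rubisco activase, stood at 1821 ± 212 against 5590 ± 499 CPM. Lower too were 8 of 11 aliphatic glucosinolate genes (adjusted p = 0.00256, and adjusted p = 0.367 with an estimated correlation) and 8 of 10 cold response genes (adjusted p = 0.0127, and adjusted p = 0.425 with an estimated correlation). COR15B, a chloroplast cold protein, stood at 100.1 ± 14.5 against 748 ± 133 CPM. The lists not called at 8 h had 1 member higher and 3 lower of 5 for growth at warm temperature (adjusted p = 0.308), 8 and 3 of 18 for the circadian clock (0.488) and 1 and 5 of 7 for ribosome biogenesis (0.149). PIF4, a growth factor active in warmth, stood at 2.27 ± 0.579 against 70.6 ± 6.70 CPM and FIB2, a fibrillarin gene, at 66.1 ± 14.1 against 389 ± 40.9.

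Of all genes tested 77.02% were called at 8 h, and markers of other cell types were not called more often. Of 13 for guard cell and epidermis 2 were higher and 6 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.0777). There were 6 lower of 10 for vascular tissue (5 adjusted over the list alone; 0.168) and 2 lower of 4 for meristem, flower and root (0.333). These lists were not called against other genes. Fry asks whether members move 1 way on balance, without setting them against other genes, and gave adjusted p = 1.19e-05, 0.0204 and 0.000451. With most genes called, fry does not set these lists apart. In all, edgeR called 6042 genes higher and 5894 lower at 8 h, 4567 and 4552 of them at least 2-fold. RLE scaling moved the median log2 change by -0.106 and total counts by -0.211. Of genes higher at 4 h, 2892 were also higher at 8 h where 1354 would be expected if the calls were independent, and of those lower 2584 where 1296 would be expected.

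**Figure D3:**
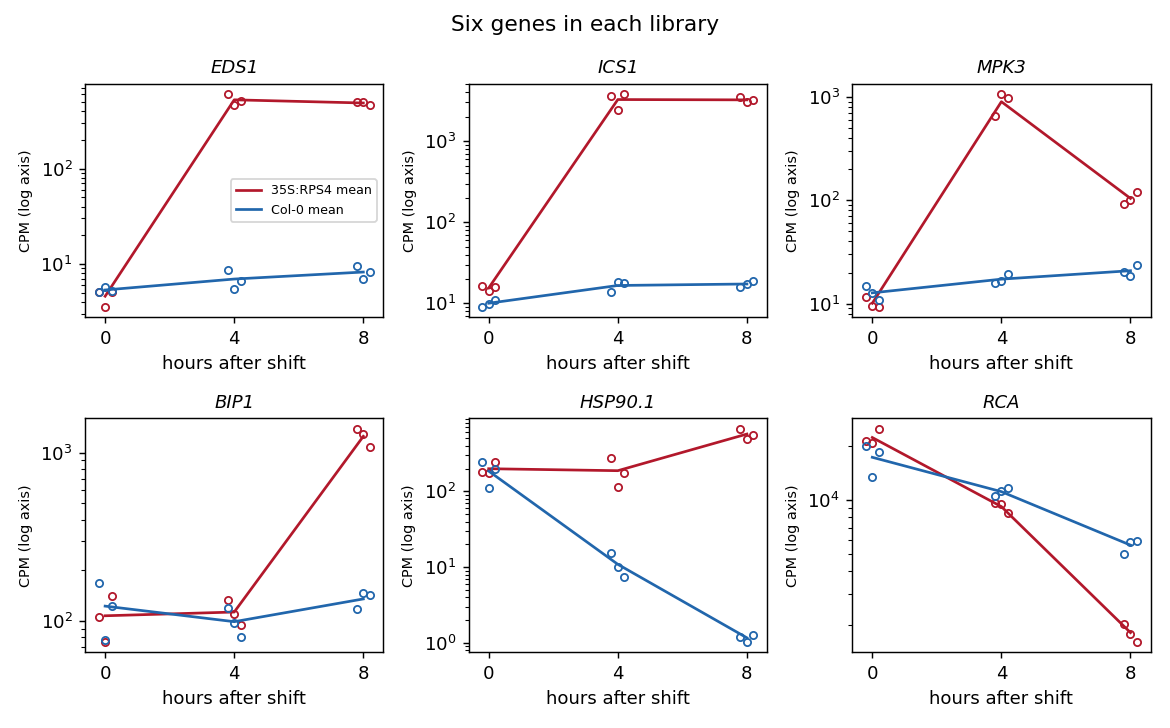
Levels in CPM of junction reads (vertical, log axes) against hours after the shift (horizontal) for EDS1, ICS1, MPK3, BIP1, HSP90.1 and RCA; points are libraries and lines join group means. MPK3 has its highest mean in 35S:RPS4 at 4 h (902 CPM) and BIP1 at 8 h (1251 CPM), while HSP90.1 falls in Col-0 to 1.17 CPM at 8 h.

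The change with time within the line asks how its transcripts moved once immunity was switched on, with the effects of the temperature shift and of the hour included. From 0 h to 4 h MPK11, a MAP kinase gene, rose 2670-fold (0.181 ± 0.0856 to 462 ± 80.6 CPM, n = 3 each). WRKY50 rose at least 1090-fold, BON3 at least 915-fold, and FLOT1, a flotillin gene, 2860-fold (95% counting interval 791 to 23600). ATSBT5.2, a subtilase gene, fell 96.6-fold, BR6OX2 71.4-fold and COL2 57.9-fold. From 0 h to 8 h UGT76B1, a glucosyltransferase acting on SA and N-hydroxypipecolic acid, rose 5680-fold, from 0.0896 to 435 ± 38.7 CPM. WRKY50 rose at least 2130-fold and MSRB7 at least 1640-fold. PDCB3 fell at least 414-fold, WSD1, a wax ester synthase gene, 1140-fold (to 0.1065 CPM) and DES1, a cysteine desulfhydrase gene, 1090-fold (to 0.058 CPM). The folds of UGT76B1, WSD1 and DES1 rest on few reads at the lower level and carry a wide counting error.

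At 4 h within the line members that rose and fell numbered 21 and 1 of 25 for SA and EDS1, 23 and 0 of 24 for WRKY and 15 and 0 of 15 for surface receptors. The NLR list had 15 and 0 of 16 (16 adjusted over the list alone), jasmonate and ethylene 12 and 0 of 19, camalexin 10 and 0 of 12 (11 adjusted over the list alone). Aliphatic glucosinolates had 0 and 10 of 11, photosynthesis 0 and 19 of 25, and cold response 8 and 0 of 10 (10 adjusted over the list alone). These 9 lists were called by camera, and with an estimated correlation the call held for SA and EDS1 (adjusted p = 0.00498), WRKY (0.00816) and surface receptors (0.0439), but not for NLR (0.0824), camalexin (0.0655), jasmonate (0.527), aliphatic glucosinolates (0.497), photosynthesis (0.525) and cold response (0.525). At 8 h 8 lists were called, ER folding with 14 and 0 of 14 for the first time, aliphatic glucosinolates with 0 and 11 of 11 and photosynthesis with 0 and 23 of 25. With an estimated correlation SA and EDS1 (24 and 1, adjusted p = 0.0185) and WRKY (23 and 0, 0.0496) were called. Lists not called with it were ER folding (0.267), surface receptors (13 and 1, 0.312), NLR (11 and 0, 0.38), camalexin (9 and 2, 0.38), aliphatic glucosinolates (0.38) and photosynthesis (0.38). Splicing factor genes went both ways at 8 h, with 12 up and 11 down of 31, and heat shock genes with 6 up and 3 down of 12. Of the lists of cell type markers camera called none at either time, while fry called some at both, as counted below. In edgeR 4026 genes rose and 4198 fell by 4 h, and 5881 rose and 5796 fell by 8 h. The rise of HSFA2, a heat shock factor, in the line at 4 h (log2 change 1.19, adjusted p = 0.0297) rests on junctions other than the main type of row, without which its log2 change was -0.111 (adjusted p = 0.895).

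In Col-0 the same shift asks what temperature and hour do without the transgene. Genes of heat shock fell and genes of cold and of the clock moved. HSP90.1 fell 17.2-fold by 4 h and 160-fold by 8 h (186 ± 68.5, 10.9 ± 3.99 and 1.17 ± 0.119 CPM at 0, 4 and 8 h, n = 3 each), and GolS1, galactinol synthase, fell 24.4-fold and 160-fold. COR15B rose 12.4-fold by 4 h (30.9 ± 18.1 to 375 ± 42.7 CPM) and 24.5-fold by 8 h. RbcX1, an assembly chaperone of Rubisco, rose 30.2-fold by 4 h and 163-fold by 8 h, and PORB, protochlorophyllide oxidoreductase, 13.8-fold by 4 h. At 8 h COR27, a cold- and clock-regulated gene, had risen 305-fold and AT4G33980 924-fold, while RVE8, a morning factor of the clock, had fallen 101-fold and HSP70-4, a chaperone gene, 284-fold.

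Of heat shock genes 9 of 12 fell at 4 h (adjusted p = 1.69e-09, and 0.0324 with an estimated correlation) and 11 of 12 at 8 h (adjusted p = 9.56e-07, and adjusted p = 0.105 with an estimated correlation). Jasmonate and ethylene genes fell in 18 of 19 at 4 h (18 down and 1 up adjusted over the list alone; adjusted p = 1.68e-07, and adjusted p = 0.622 with an estimated correlation). At 8 h 16 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.000297, and adjusted p = 0.866 with an estimated correlation). JAZ10, a jasmonate repressor gene, went from 58.1 ± 53.1 to 1.69 ± 1.36 CPM by 4 h, and the 0 h libraries of Col-0 were uneven in it, as in TAT3 (224 ± 220.0 CPM). Cold response genes rose in 5 and fell in 1 of 10 at 4 h (6 and 1 adjusted over the list alone; adjusted p = 0.000715, and adjusted p = 0.622 with an estimated correlation). At 8 h 7 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.866 with an estimated correlation). Ribosome biogenesis genes rose in 6 of 7 and 5 of 7 (adjusted p = 7.53e-06 and 0.00277, and adjusted p = 0.289 and 0.647 with an estimated correlation), with NUC1, a nucleolin gene, at 993 ± 148, 2457 ± 326 and 2996 ± 245 CPM. Aliphatic glucosinolate genes fell in 3 and 8 of 11 (5 and 9 adjusted over the list alone; adjusted p = 0.0324 and 0.0121, and adjusted p = 0.693 and 0.866 with an estimated correlation). Splicing factor genes rose in 2 and fell in 18 of 31 at 8 h (2 and 19 adjusted over the list alone; adjusted p = 0.00303, and adjusted p = 0.541 with an estimated correlation), SR30 from 380.5 ± 49.4 to 67.9 ± 8.75 CPM. All 18 measured clock genes changed by 8 h, 10 up and 8 down: TOC1 rose 19.8-fold and CCA1 fell 61.3-fold. The list was not called in 1 direction (adjusted p = 0.786). Immune lists were not called at either time: SA and EDS1 had 2 members up and 5 down at 4 h and 6 and 4 at 8 h, and WRKY 1 and 2, then 3 and 2. Of the lists of cell type markers camera called none, while fry called 1 at each time. EdgeR called 1557 genes up and 2019 down by 4 h, and 3320 and 3747 by 8 h. The balance depends on scaling: with total counts the share up went from 43.5% to 61.5% at 4 h (shift of the median 0.111) and from 47% to 53.2% at 8 h, and with RLE at 8 h to 51%. No plants kept at 28 °C were sampled at 4 h or 8 h, so the effects of temperature and of time of day cannot be separated. Without Col-0 4 h replicate 2, 2341 genes were called at 4 h. Removal of Col-0 0 h replicate 2 and 8 h replicates 2 and 3 left only replicate 1 at 8 h, so its count at 8 h is not given.

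The difference between the responses of the lines, tested as an interaction, asks which changes went beyond those of Col-0. At 4 h AT1G10340 rose more in the line by 12.38 on the log2 scale (SE 1.2, adjusted p = 5.87e-07), WRKY50 by 12.94 (SE 2.67, adjusted p = 0.00161) and BON3 by 15.60 (SE 3.41, adjusted p = 0.00336). ACL5 responded by -6.18 (SE 0.736, adjusted p = 5.53e-06), BR6OX2 by -5.32 (SE 0.476, adjusted p = 2.16e-07) and HBI1 by -4.41 (SE 0.584, adjusted p = 1.77e-05), all relative to Col-0. At 8 h ABO3, a WRKY factor gene, differed by 13.87 (SE 1.27, adjusted p = 6.51e-08), UGT76B1 by 13.78 (SE 1.42, adjusted p = 2.57e-07) and TAT3 by 13.20 (SE 1.32, adjusted p = 1.73e-07). In Col-0 TAT3 stood at 17.71, 454.8 and 198.1 CPM in the 0 h libraries and at a mean of 8.19 at 8 h. Its difference therefore holds a fall in Col-0 from uneven 0 h levels. Lower responses were those of PDLP3 by -10.84 (SE 0.612, adjusted p = 3.7e-10), EXPA11 by -11.96 (SE 1.02, adjusted p = 8.78e-08) and XTH31, a cell wall enzyme gene, by -9.75 (SE 0.700, adjusted p = 4.02e-09). Fitted values of genes with a group at 0, such as BON3, WRKY50 and EXPA11, depend on the prior count and are no bound.

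Members with a higher or lower response than in Col-0 at 4 h numbered 21 and 0 for SA and EDS1, 21 and 0 for WRKY, 14 and 0 for surface receptors and 14 and 0 for NLR (15 adjusted over the list alone). They were 15 and 0 for jasmonate and ethylene (17 adjusted over the list alone), 8 and 0 for camalexin (11 adjusted over the list alone), 7 and 0 for heat shock (10 adjusted over the list alone) and 7 and 1 for senescence. Aliphatic glucosinolates had 1 and 6 and photosynthesis 0 and 6 (4 adjusted over the list alone). Camera called these 10 lists. With an estimated correlation it called SA and EDS1 (adjusted p = 0.00142), WRKY (0.0053), surface receptors (0.0217) and camalexin (0.0256), but not NLR (0.0696), heat shock (0.123), senescence (0.2), jasmonate (0.242), aliphatic glucosinolates (0.551) or photosynthesis (0.551). Of the 370 genes that rose in the line and fell in Col-0 by 4 h, 11 were on the jasmonate list. Levels of that list at 0 h in Col-0 were 2.24 and 2.13 in replicates 2 and 3 and -0.49 in replicate 1, and at 4 h -1.42, -0.91 and -2.07. Against the line's 0 h libraries 2 of 19 members were lower in Col-0 at 4 h. At 8 h ER folding joined, with 14 and 0 of 14, and photosynthesis had 0 and 21 of 25, heat shock 11 and 0 of 12 and splicing factors 14 and 1 of 31 (12 and 0 adjusted over the list alone; adjusted p = 0.0522, not called). Of the 11 lists called at 8 h only SA and EDS1 (24 and 0) was called with an estimated correlation (adjusted p = 0.0155). For WRKY (20 and 0, 21 adjusted over the list alone) it was adjusted p = 0.0612, for ER folding and heat shock 0.23 and for surface receptors 0.237. It was 0.276 for senescence, 0.284 for photosynthesis, NLR and camalexin, 0.408 for aliphatic glucosinolates and 0.491 for jasmonate. GRP7, an RNA-binding clock output gene, reached 3284 ± 804 CPM in Col-0 at 8 h and 285 ± 31.1 in the line, a difference of -3.52 in log2 response (SE 0.407, adjusted p = 9.68e-07). EdgeR called 2710 genes with a higher and 2334 with a lower response at 4 h, and 5220 and 5117 at 8 h. Scaling by total counts moved the share with a higher response at 4 h from 53.7% to 39.2%.

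Splicing was compared as the use of each junction or retained intron relative to the rest of its gene, over 104357 features of 13393 genes. Before the shift 11 genes passed, none of them with a retained intron as the lowest-p feature, and in 8 that feature was a junction missing from at least 1 library's table; with such junctions left out 0 genes passed. RLM3, a TIR-domain gene, had 0 reads over the junction at chromosome 4, 9562886 to 9563017, in the line at 0 h and in Col-0 at 8 h, and 967 to 2772 reads in each of the other groups. At this time 162 genes had an unadjusted p under 0.05.

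At 4 h 423 genes differed in splicing between the lines, and for 331 of them the lowest-p feature was a retained intron, lower in the line in 256. In 16 of the 423 the lowest-p feature was a junction missing from at least 1 library's table. Without 35S:RPS4 4 h replicate 3 the count of genes called was 227 and without Col-0 4 h replicate 3 it was 262, and with splice junctions only it was 46. Photosynthesis genes were the group most concerned: 23 of 25 tested were called, more than among other genes (Fisher's exact test, adjusted p = 9.64e-32). Genes were not matched for read depth in this test or in those on lists below. Low retained shares can be called only with many reads, so depth may account for part of such an excess. The intron at chromosome 5, 2993905 to 2993977, of PMDH2 (AT5G09660), peroxisomal malate dehydrogenase, was retained in 0.227% ± 0.0946 of the reads over it in the line and in 2.56% ± 0.622 in Col-0 (log2 difference in use -3.46, SE 0.285). That of FBA1 (AT2G21330), an aldolase of the Calvin cycle, at chromosome 2, 9128695 to 9128776, was retained in 0.112% ± 0.0204 and 1.67% ± 0.468. The opposite was found in SCL30 (AT3G55460), an SR-like splicing factor, whose intron at chromosome 3, 20563315 to 20563399, was retained in 31.4% ± 11.8 in the line and 3.05% ± 0.201 in Col-0 (log2 difference 3.75, SE 0.388, gene adjusted p = 1.22e-13). PIS2 (AT4G38570), a phosphatidylinositol synthase, had 88.3% ± 4.61 and 2.87% ± 2.53 retained at chromosome 4, 18031673 to 18031761. NUDT7 (AT4G12720), a negative regulator of EDS1 signalling, had the lowest gene p (adjusted p = 5.21e-30). Reads retained at chromosome 4, 7487450 to 7487540, were 0.0269% ± 0.00322 of the gene's reads in the line and 5.62% ± 0.807 in Col-0, while their number was 153 and 204. Of the reads over that intron itself 85.9% ± 4.59 were retained in the line and 75.2% ± 8.05 in Col-0, so the lower use is relative to the gene's other reads.

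At 8 h 550 genes differed, 305 with a retained intron as the lowest-p feature, which was lower in the line in 230, and 24 of 25 photosynthesis genes were among them (adjusted p = 1.56e-31). CA1 (AT3G01500), a carbonic anhydrase, retained the intron at chromosome 3, 195338 to 195405, in 0.372% ± 0.0904 of reads in the line and 7.43% ± 0.542 in Col-0, and PMDH2 0.106% ± 0.0312 and 2.42% ± 0.178. SCL30 had 26.4% ± 2.33 and 2.71% ± 0.512 (adjusted p = 2.09e-11). Of listed NLR genes RPP5 passed (adjusted p = 0.0332). Its junction at chromosome 4, 9543736 to 9543861, held 10.1% ± 1.37 of the gene's reads in the line and 4.38% ± 5.05 in Col-0. The Col-0 libraries were thus uneven in it. In Col-0 8 h replicates 2 and 3 reads were spread along genes unlike in replicate 1 (scores on the main axis of coverage 1.36 and 0.84, against -0.41), and Col-0 0 h replicate 2 had the next score, 0.6, and without replicate 1 the count was 2000. Without 35S:RPS4 8 h replicates 1, 2 or 3 it was 322, 327 or 352, and with splice junctions only 194. In 50 of the 550 genes the lowest-p feature was a junction missing from at least 1 library's table, and with such junctions left out 531 genes were called.

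**Figure D4:**
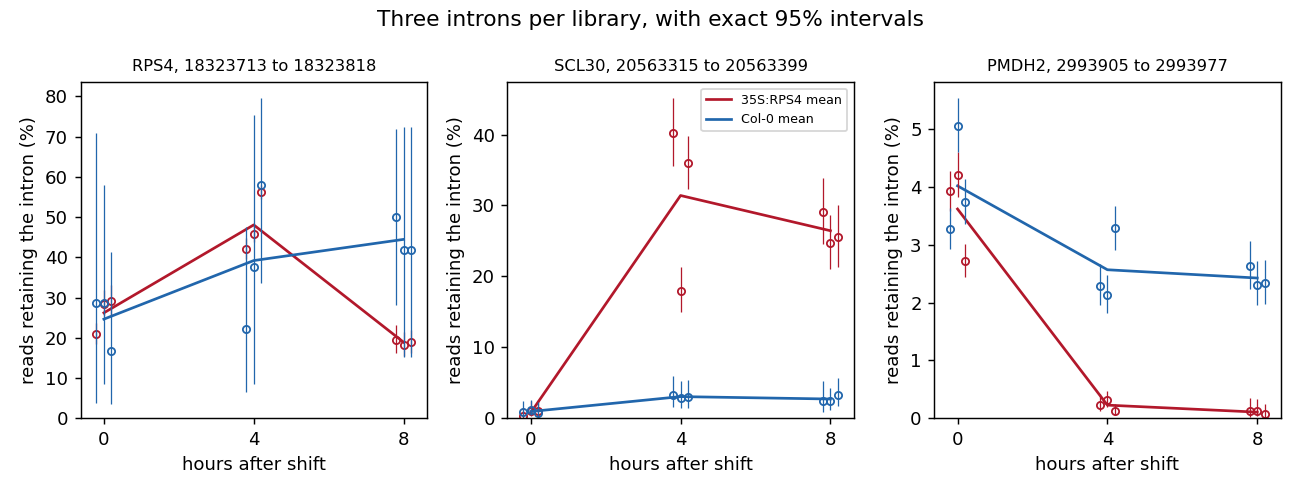
Percent of reads over an intron that were retained (vertical) by line and time (horizontal) for RPS4, SCL30 and PMDH2; points are libraries with exact 95% binomial intervals and lines are group means. In 35S:RPS4 the SCL30 mean goes from 0.771% at 0 h to 31.4% at 4 h, and that of PMDH2 from 3.61% to 0.227%.

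Within the line 640 genes were called by the splicing test by 4 h and 872 by 8 h. Of photosynthesis genes 25 of 25 were called at both times (Fisher's exact test, adjusted p = 1.22e-32 and 3.16e-29). The lowest-p feature was a retained intron in 435 and 503 of the called genes. In 36 and 54 it was a junction missing from at least 1 library's table. These calls concern use within a gene, and changed splicing in the line remains a hypothesis, as weighed below. Ribosome biogenesis genes passed at 4 h (3 of 7, adjusted p = 0.0329). SCL30 went from 0.771% ± 0.452 to 31.4% ± 11.8 retained (log2 change in use 5.68). The counts were 395 without 35S:RPS4 4 h replicate 3, and 568 and 558 without 8 h replicates 1 and 2, and with splice junctions only 149 and 333. In Col-0 74 genes were called by 4 h and 287 by 8 h. These counts moved with single libraries: at 4 h to 30, 33 and 46 without Col-0 4 h replicates 1, 2 and 3 and to 42 without 0 h replicate 2, and at 8 h to 870, 171 and 168 without 8 h replicates 1, 2 and 3. With splice junctions only they were 45 and 87. In 20 of the 74 genes and 30 of the 287 the lowest-p feature was a junction missing from at least 1 library's table. Among the changes in Col-0 were those in HYH, a bZIP factor of light signalling, whose A3P junction at chromosome 3, 6024035 to 6024152, fell from 10.8% ± 2.2 to 2.53% ± 0.759 of the gene's reads by 4 h. In SCL33, an SR-like splicing factor gene, the A5P junction at chromosome 1, 20631723 to 20631884, rose from 1.32% ± 0.400 to 6.41% ± 0.922. By 8 h in Col-0 retained introns of LHCA1 and LHCB3, light-harvesting genes, fell from 1.18% ± 0.542 to 0.127% ± 0.00743 and from 2.63% ± 1.32 to 0.218% ± 0.0432, and 14 of 25 photosynthesis genes were called (adjusted p = 2.26e-16). Clock (3 of 17, adjusted p = 0.0353), splicing factor (4 of 31, 0.0353) and ribosome biogenesis genes (2 of 7, 0.0448) also passed there. The codes A3P and A5P are not explained in the sources used here; in the tables such junctions share only their lower or only their upper coordinate with a main junction. Splicing responses differed between the lines for 179 genes at 4 h and 267 at 8 h, among them 17 and 21 of 25 photosynthesis genes (adjusted p = 1.26e-25 and 2.1e-31) and SCL30 (adjusted p = 0.000874 and 0.00345). The first count was 113 without 35S:RPS4 0 h replicate 2, 118 without 4 h replicate 3 and 116 without Col-0 4 h replicate 3, the second 812 without Col-0 8 h replicate 1, and with splice junctions only they were 26 and 81. In 19 of the 179 genes and 37 of the 267 the lowest-p feature was a junction missing from at least 1 library's table.

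RPS4 transcripts changed splicing in the line by 4 h (gene adjusted p = 2.99e-05), where reads of the transgene and of the native gene were not told apart. The A5P junction of RPS4 at chromosome 5, 18323436 to 18323818, had 4 reads at 0 h, 234 at 4 h and 16 at 8 h over the 3 libraries. At 4 h this was 0.947% ± 0.305 of the gene's reads. Col-0 had 0 such reads, but only 40 to 73 RPS4 junction reads per library against 2251 to 8337 in the line. The 0 in Col-0 therefore does not show that the junction is particular to the line. The intron at 18323713 to 18323818 was retained in 26.2% ± 4.58 of reads at 0 h, 48.1% ± 7.32 at 4 h and 18.9% ± 0.557 at 8 h (4 h against 0 h, log2 change in use 1.15, SE 0.276, adjusted p = 0.00708). In Col-0 the means were 24.6% ± 6.87, 39.2% ± 17.9 and 44.4% ± 4.81, from 9, 18 and 21 retained reads over the group. No RPS4 splicing difference passed in any other comparison (adjusted p from 0.389 to 1).

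Over 10421 introns together the share of retained reads was 2.40% ± 0.459, 3.00% ± 0.389 and 2.40% ± 0.178 in the line and 2.75% ± 0.819, 2.48% ± 0.338 and 2% ± 0.0838 in Col-0 at 0, 4 and 8 h. Retention was then set against the change in spliced transcript of its gene. Introns of genes that rose over 4-fold by 4 h in replicate 1 had a median log2 change of 1.18 in retention in replicates 2 and 3 (564 introns). The median was -1.19 for introns of genes that fell over 4-fold (333 introns), and for those of genes that changed by under 1.4-fold it was -0.50 (2295 introns). By 8 h these medians were 0.19, -1.85 and -0.38. In Col-0 they were 0.72 (86 introns), -0.78 (91 introns) and -0.07 at 4 h, and -0.15, -0.71 and -0.38 at 8 h. Spearman's rho across introns was 0.46 at 4 h and 0.426 at 8 h in the line, and 0.0549 and 0.0746 in Col-0, where introns of 1 gene are not independent. With the roles of the replicates exchanged it was 0.48 and 0.55 in the line and 0.12 and 0.124 in Col-0. Introns were kept by their retained reads over both times, which can raise rho and spread the medians by class.

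**Figure D5:**
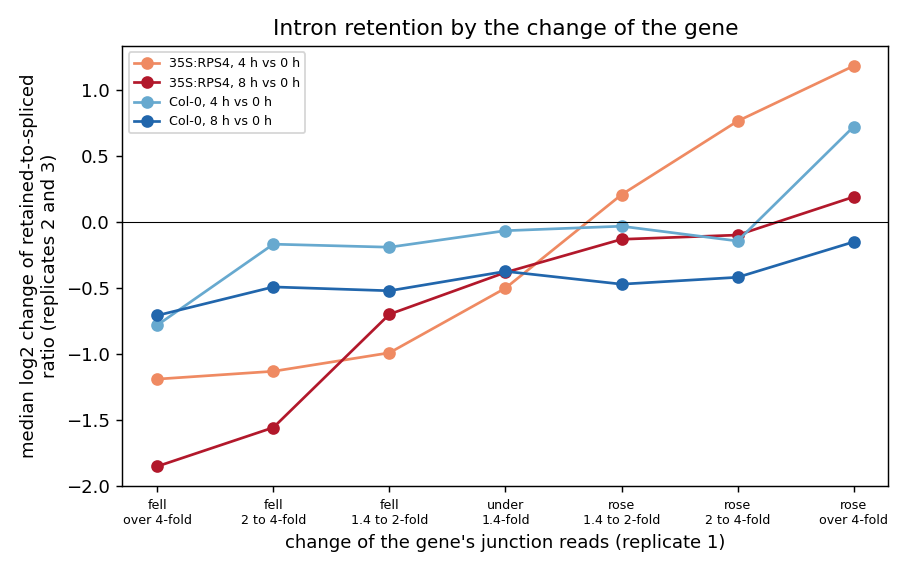
Median log2 change in the ratio of retained to spliced reads in replicates 2 and 3 (vertical) against the class of change of the gene's junction reads in replicate 1 (horizontal), with 1 line for each line of plants and time. In 35S:RPS4 at 4 h the median goes from -1.19 in genes that fell over 4-fold to 1.18 in those that rose over 4-fold.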

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

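The tests on jasmonate genes were written after their result was seen, and the rule for reading the comparison with the line's 0 h libraries was made stricter after its first value; the tests on coverage, on retention and on splits of the libraries were written before their values were seen, after the patterns had been noticed in the same data.

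Responses differed between the lines for 5044 genes at 4 h and 10337 at 8 h, and for splicing in 179 and 267 genes. Camera with the preset correlation called 10 lists at 4 h and 11 at 8 h, and with an estimated correlation 4 and 1. By 4 h 370 genes rose in 35S:RPS4 and fell in Col-0 and 147 the reverse, and by 8 h 1107 and 1123. If calls were independent 524.5 and 421.8 would be expected at 4 h and 1422 and 1242 at 8 h, so all 4 counts lie below these. Of the 1107, 5 were heat shock, 4 surface receptor, 4 splicing factor, 3 SA and EDS1 and 3 jasmonate genes, and other lists had 2 or fewer; of the 1123, 2 were ribosome biogenesis genes, and other lists had 1 or 0. The RPS4 transcript itself rose more in the line by 0.965 on the log2 scale at 4 h. Features whose rows name several genes were left out of the gene sums; tested apart, 299 of 714 differed between the lines at 8 h (148 higher, 151 lower), 173 at 4 h and 0 at 0 h by edgeR.

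Splicing calls between the lines at 8 h went from 550 to 2000 when Col-0 8 h replicate 1 was left out. Replicates 2 and 3 of that group share a spread of reads along genes, with scores of 1.36 and 0.84 on an axis holding 74.1% of the variance of coverage over 2681 genes, where Col-0 0 h replicate 2 had 0.6 and the others -0.48 to 0.34. With features compared only with those sharing an end, calls without replicate 1 were 0.987 of those with it (462 and 468), which suggests that uneven coverage may be behind the rise. With junctions of missing rows left out the ratio was 3.71, which speaks against those junctions as its source. A difference in the leaves themselves was not tested and stays open.

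Between retention and transcript change in the line Spearman's rho across introns was 0.426 at 8 h. A share of unspliced RNA that moves with the transcript, for example through recent synthesis, would give a positive rho. The rate of synthesis was not measured. A constant background such as genomic DNA would by itself give a negative rho. Introns were kept by their retained reads over both times, which can push rho upward. Under the same rule rho in Col-0 was 0.0746 at 8 h. How far the selection moved rho was not measured, so 0.426 does not decide between a moving share and such a background. The median over all introns was 0.12 of that over introns called lower (-0.50 and -4.17), but the latter were picked for low values, so this ratio tests nothing. Apart from the selection of introns, a shift alike in all of them would not give class medians from -1.85 to 0.19 at 8 h. Pooled retention was 2.40% at 0 h and at 8 h. Whether part of the overall median is library-wide stays open, and changed splicing in the line remains a hypothesis, found and tested on the same data.

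Jasmonate genes were high in 2 of 3 Col-0 libraries at 0 h (replicates 2 and 3, 2.24 and 2.13; replicate 1, -0.49). Without replicate 2 the list's median log2 change in Col-0 at 4 h was -2.96 and 13 of 19 members fell, but replicate 3 stood as high, so this leaves raised libraries open. Against the 0 h libraries of the line the median was -1.29, with 2 of 19 members called, so raised 0 h libraries of Col-0, from handling or from the plants, may account for part of the fall; the difference of library means was -1.13 with SE 0.52. Whether genotype, wounding or harvest set these levels was not tested.

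Other splits of the same libraries were refitted. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In genes the real split alone (1 of 10) gave as many calls in each: 2 at 0 h, 7244 at 4 h and 11304 at 8 h between the lines, 7454 and 11497 with time in 35S:RPS4 and 3166 and 5299 in Col-0, with 0 as the highest other in all 7. In splicing 2 of 10 gave as many at 0 h (real 5, highest other 6), and 1 of 10 elsewhere, with 527 (highest other 2) and 401 (2) between the lines, 669 (3) and 1017 (1) in 35S:RPS4 and 105 (6) and 107 (16) in Col-0. For the difference of responses at 4 h 4 of 100 splits gave as many genes (real 4999, highest other 5561). At 8 h it was 3 of 100 (9957, 9964), both under 0.05. All of these kept the later groups apart, and with those groups mixed the highest was 0 and 1. Of the splits that kept them apart, 4 of 11 at 4 h and 3 of 13 at 8 h gave as many. For splicing 3 of 21 splits gave as many at 4 h (real 208, highest other 246). The 3 kept the later groups apart (highest with them mixed 12). At 8 h it was 1 of 21 (242, 224), under 0.05 but the lowest share that 21 splits allow, and 2 of the 21 kept the later groups apart. These shares follow whether the later groups stay apart. They decide nothing about the difference of responses, and chance is not excluded for it.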

How the results depend on the processing

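Tests of 3 removed libraries, total counts, changed gene sums, missing rows and splice junctions only were chosen after results were seen. Of 495 values of 45 results 426 were the same and 66 moved. For counts of genes or lists, same means within 1.5 times, which does not show that the same members were called. Calls and signs apply only to results on the RPS4 transcript, where same means that call and direction were kept. There a call was lost in 1 value and gained in 2, and 0 changed sign. Causes of the moves were not tested, apart from the rise from 550 to 2000 splicing calls weighed above. Of 27400 values of named genes 26248 kept call and direction, 1151 lost the call and 1 changed sign, that of HSFA2 in the line at 4 h with NJ junctions only (-0.111). Depth limited splicing to features of at least 10 reads.

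Among gene counts, DESeq2 gave 115 at 0 h, where leaving out 1 library gave 2 to 194 (194 without Col-0 0 h replicate 1). In Col-0 at 4 h leaving out 1 library gave 2341 (without 4 h replicate 2) to 3459, and at 8 h removal of 3 doubted Col-0 libraries gave 4560. The RPS4 response at 4 h was 0.755 with total counts only. At 8 h it ranged from -0.685 to -0.335, called without Col-0 8 h replicate 2 (-0.685) and without 35S:RPS4 0 h replicate 3 (-0.664). Replicate numbers showed little pairing in gene levels (r of the same number, median 0.0215, maximum 0.4, over 0.1 in 10 of 45 pairs; 8 of 18 libraries were closest to their own number). In coverage along genes, though, replicate 1 had the lowest score in all 6 groups, so a shared effect of number there is open. As a block they gave 7028 genes at 4 h and 12030 at 8 h between the lines, and 433 and 706 in splicing.

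In splicing at 0 h, a minimum of 30 reads gave 7, only the groups compared 5, features sharing an end 4, missing rows left out 0, and leaving out 1 library 6 to 10. With splice junctions only there were 46 at 4 h and 194 at 8 h between the lines, 149 and 333 with time in 35S:RPS4, 45 and 87 in Col-0, and 26 and 81 for the difference. A minimum of 30 reads gave 366 at 8 h between the lines and 556 in 35S:RPS4 at 8 h. Removal of the 3 libraries gave 315 at 8 h between the lines and 80 in Col-0 at 8 h, and only the groups compared 107 there.

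Leaving out 1 library gave these splicing counts. At 4 h between the lines 227 (without 35S:RPS4 4 h replicate 3) to 320, with 262 without Col-0 4 h replicate 3. At 8 h 322 (without 35S:RPS4 8 h replicate 1), 327 (replicate 2) and 352 (replicate 3) to 2000 (without Col-0 8 h replicate 1). In 35S:RPS4 395 (without 4 h replicate 3) to 534 at 4 h, and 558 (without 8 h replicate 2) and 568 (replicate 1) to 749 at 8 h. In Col-0 30, 33 and 46 (without 4 h replicates 1, 2 and 3) and 42 (without 0 h replicate 2) to 68 at 4 h, and 168, 171 and 870 (without 8 h replicates 3, 2 and 1) at 8 h. For the difference 113 (without 35S:RPS4 0 h replicate 2), 116 (Col-0 4 h replicate 3) and 118 (35S:RPS4 4 h replicate 3) to 182 at 4 h, and 192 to 812 (without Col-0 8 h replicate 1) at 8 h.

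Lists called by camera with an estimated correlation numbered 0 at 0 h, 4 at 4 h and 1 at 8 h between the lines, 3 and 2 in 35S:RPS4, 1 and 0 in Col-0, and 4 and 1 for the difference. Fry called 0 at 0 h, 16 at 4 h and 19 at 8 h, 15 and 15 in 35S:RPS4, 8 in Col-0 at 4 h, and 17 for the difference at 8 h. Of the 3 lists of cell type markers fry called 2 at 4 h and 3 at 8 h, 2 and 3 in 35S:RPS4, 1 and 1 in Col-0, and 1 and 2 for the difference, where camera called 0. Fry does not set a list against other genes, so its calls do not set these lists apart.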

Other observations

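Among tests named here, those on whole missing rows and on genes shared between lines were chosen after results were seen; that on the share gained by other junctions was written before. Changes with time were also compared between the lines. Of genes that rose by 4 h, 835 rose in both lines where 404.5 would be expected if calls were independent, and of those that fell 1081 where 546.9 would be expected. By 8 h the shared numbers were closer to those expected, 1433 against 1260 for genes that rose and 1858 against 1401 for genes that fell. PRR5, a clock gene, rose in both lines, to 94.2 ± 3.62 CPM in 35S:RPS4 and 115 ± 32.5 in Col-0 at 8 h. WRKY54 rose in Col-0 too, 11.5-fold by 4 h, to 9.61 ± 7.56 CPM against 116 ± 13.1 in the line.

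AT1G53450 had 91.5% ± 3.82 of its reads as retained reads at chromosome 1, 19951482 to 19951740, in the line at 4 h and 5.98% ± 1.18 in Col-0. CYP38, a chloroplast cyclophilin, had 7.24% ± 1.34 of its reads on the A3P junction at chromosome 3, 189628 to 189712, at 0 h in the line. By 8 h this share was 0.0939%, a log2 change in use of -6.15.

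Junctions missing from single tables were examined as well, and were set aside from the patterns weighed above after their values were seen. There were 1237 zero values where at least 20 reads were expected, in 519 junctions of 410 genes, against 482 values above 0 and up to 10% of the expected, 2.57 zeros per such value. Col-0 8 h replicates 2 and 3 had 202 and 117, the other libraries 45 to 70. Of the 519 junctions 322 were missing in 1 library and 53 in a whole group. Of the 519, 209 had no junction sharing an end that could gain their reads, and 57 of the others gained at least 50%. Over all missing reads pooled the share gained was 12.2%. The median share over junctions was 0, and -0.00213 where a junction sharing an end existed. For the most part the missing reads thus did not turn up on junctions sharing an end. Other causes were not tested.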
